A study of Mus musculus with 4 samples.

How the data were processed

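RNA sequencing libraries were made from mouse intestinal organoids, self-organising epithelial cultures grown from intestinal tissue, of wild-type C57BL/6 mice aged 8 to 12 weeks. Per the labels' protocols, total RNA was taken 36 hours after 8 Gy of irradiation from organoids given vehicle or SGC-CBP30, and libraries were made with a NEBNext kit. SGC-CBP30 is a small molecule that binds the bromodomains, the acetyl-lysine reading domains, of the related acetyltransferases CBP and p300. Each group held 2 libraries, 4 in all, and no unirradiated group was analysed here. One SGC-CBP30 library, replicate 2, carries the compound name SGC-CBP31 in its treatment label. It was placed with SGC-CBP30 by its title and by the stated group size of 2, and the results without it were also computed. Nothing in the labels says whether the replicates are separate cultures or animals, so all p-values measure the spread between these libraries only, which may be technical.

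The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 without their roles. They name the genome build mm9. The gene coordinates in the deposited table are those of GRCm38, however: of 51477 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 98.5% had identical coordinates, and 32 identifiers were not in that annotation. Coordinates are therefore given as GRCm38, 1-based. Strand use and the handling of reads that map to several places are not given in the sources used here. Genes with near-identical copies (alpha-defensins, Reg3, Cyp2c, Cyp3a, Ces1, Slc5a4a with Slc5a4b, histocompatibility genes, and mitochondrial genes with nuclear copies) and genes that overlap an antisense partner therefore have uncertain counts.

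All values came from 1 deposited table, whose columns held raw counts, FPKM, group means and the authors' comparison. Per the file headers, the authors gave whole-number counts per gene and library, and these deposited counts had not been normalized. The deposited FPKM values equal the count divided by gene length and by a scaled library total, and the deposited gene length in bases is the length the authors used. The authors' group means are a signal value on the scale of normalized counts, each count divided by 1 size factor per library. Per the file headers, the authors also gave a log2 fold change of SGC-CBP30 over vehicle, and with it a deposited p-value and adjusted p-value from a test they do not name. The table was held in part: it stops within its last line. It lists 51509 genes, of which the first 26144 have at least 1 count and the 25365 after them have none in any library. Genes after that point were not used here. The table held 27 symbols turned into dates, and all 27 were restored through the gene identifier. Only the counts and the gene annotation entered the tests. FPKM and group means were used to learn how the table was made, and the authors' comparison was set beside the present one.

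The libraries held 18087250 and 16433117 counts for vehicle and 16674571 and 17076724 for SGC-CBP30. At these depths, 3 counts, taken as the floor for a gene with none, equal 0.166 to 0.183 CPM, counts scaled to library size, per library. Counting intervals and floors cover counting error only. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.07 for vehicle and 6.76 for SGC-CBP30, so no library was treated as a duplicate.

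Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM normalization (factors 0.978, 0.972, 1.02 and 1.03 in the order above), robust dispersion estimates, and the quasi-likelihood F test of SGC-CBP30 against vehicle with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and 14684 genes were tested. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM are normalized with the TMM factors and given as mean ± SD (n = 2 per group). No covariate was used. Before the data were examined, the design, the alternatives, 33 gene lists and the rule for named genes were fixed. That rule names Crebbp, Ep300 and Trp53; the 10 genes highest and the 10 lowest by fold change among those called with a mean log2 CPM of at least 3 and non-overlapping groups, leaving out pseudogenes and unnamed or clone-named genes; up to 3 called members of smallest p in each list, or the 1 of smallest p where none was called; and 1 more of largest change in lists that changed. It gave 119 genes, some of which are not reported here. Others are said to be chosen after their values were seen.

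Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A list needed 5 tested members, which 30 lists had. The lists were p53 targets, pro-apoptotic effectors, anti-apoptotic genes, S phase, G2 and mitosis, double-strand break repair, Lgr5 crypt base stem cells, reserve and revival stem cells, YAP targets, Wnt/beta-catenin targets, the Notch pathway, Paneth, goblet, enteroendocrine and tuft cells, enterocytes, distal small intestine and colon, interferon-stimulated genes, antigen presentation, NF-kB and inflammation, AP-1 and immediate early genes, NRF2 antioxidant genes, the unfolded protein response, cholesterol synthesis, fatty acid oxidation and ketones, glycolysis and hypoxia, the circadian clock, bromodomain and acetyltransferase genes, mesenchymal, blood and immune, and endothelial and neural cells, ribosomal proteins, and mitochondrially encoded genes. Members were also counted with p-values adjusted over the list alone.

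The method was tested on simulated data: counts for this comparison drawn at the real means and library sizes with 200 genes changed. Over 14364 genes edgeR made 153 calls, of which 142 were true and 11 false (7.19%), and it made 6 calls when nothing had been changed. Of 50 genes per size it found 22% at 1.25-fold, 66% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. DESeq2 made 133 calls with 5 false, and limma-voom 152 with 12 false. In a simulation over 14351 genes with 10 lists of 25 genes shifted by 0.3 on the log2 scale, camera with the preset correlation found 10 and called 1 of 30 unshifted lists, whereas camera with an estimated correlation found 0 of the 10. Each simulated gene was drawn independently, so this did not test the preset correlation on genes that vary together. The gene simulation changed 200 genes, against 4401 called in the data, so its cutoff in unadjusted p was stricter. Its shares of genes found and of false calls need not hold for the data.

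The alternatives were DESeq2 size factors or library totals in place of TMM, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 50 counts in 2 libraries, the replicate number as a block, protein-coding genes only, each library left out in turn, a stricter threshold of 0.01, a minimum change of 2-fold, and camera with an estimated correlation or fry for the lists. After the data were seen, 2 more were added for the lists: camera after removal of the genome-wide trend of log2 fold change on gene length, GC content and level (splines over the 14673 genes with a GC value), and cameraPR on the fold changes themselves. In the fits that leave out a library, the lone library of a group is assumed to vary like the pair in the other.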

Results

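Gene expression was measured by RNA sequencing in irradiated mouse intestinal organoids given vehicle or the CBP/p300 bromodomain inhibitor SGC-CBP30, with 2 libraries per group, 36 hours after 8 Gy. The libraries held 16433117 to 18087250 counts, with 20980 to 21933 genes detected in each. Replicates lay close together, with Pearson correlations of log2 CPM across genes, which are not independent replicates, of 0.989 within either group and 0.971 to 0.973 between groups. The first principal component held 68.7% of the variance and separated the groups. Mitochondrially encoded transcripts took 6.64% ± 0.127 of counts in vehicle libraries and 5.62% ± 0.528 in SGC-CBP30 libraries (SD, n = 2).

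The comparison asks which transcripts differ between irradiated organoids given the inhibitor and those given vehicle. The genes that fell most under SGC-CBP30 included channels, transporters and dehydrogenases. Aqp8, a water channel of the intestinal surface epithelium, was 41.3-fold lower, from 85.2 ± 2.15 CPM to 2.06 ± 0.496 CPM (SD, n = 2). The nucleoside transporter gene Slc28a1 was 14.1-fold lower and the retinol and alcohol dehydrogenase genes Rdh16, Rdh7 and Adh4 were 19.8-fold, 10.02-fold and 12.4-fold lower. Those that rose most included genes of drug and xenobiotic metabolism: the cytochrome P450 genes Cyp2c55, Cyp2c29 and Cyp3a11 were 5.11-fold, 3.48-fold and 3.17-fold higher. Over the whole cytochrome P450 family, however, 21 of 46 tested genes fell and 11 rose, a family count made after the results were seen.

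In all, 4401 of 14684 genes (29.97%) changed, 2004 of them higher and 2397 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 5745 had an unadjusted p under 0.05. Most changes were small. The median absolute log2 fold change of the called genes was 0.48, 2630 of them (59.8%) changed by less than 1.5-fold, and 224 were at least 2-fold higher against 647 at least 2-fold lower. The groups did not overlap in 63.1% of all tested genes, against 33.3% by chance. The authors' deposited table holds 2728 genes under an adjusted p of 0.05, 1075 higher and 1653 lower, of which 2724 were also called here with the same sign. Scaling by library totals alone moved the split to 2907 higher and 1924 lower, and DESeq2 called 2722 genes, 1070 of them higher. Without vehicle replicate 2 the count was 2899, with 1235 higher, and without vehicle replicate 1 it was 2996, with 1236 higher. Of the 30 gene lists described in what follows camera called 10, 9 lower and 1 higher. With an estimated correlation it called 0, but that setting also found 0 of 10 shifted lists in simulated data. CameraPR, which was added after the data were seen, compares fold changes by size without each gene's spread. It called 1 list, the markers of the distal small intestine and colon.

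**Figure D1:**
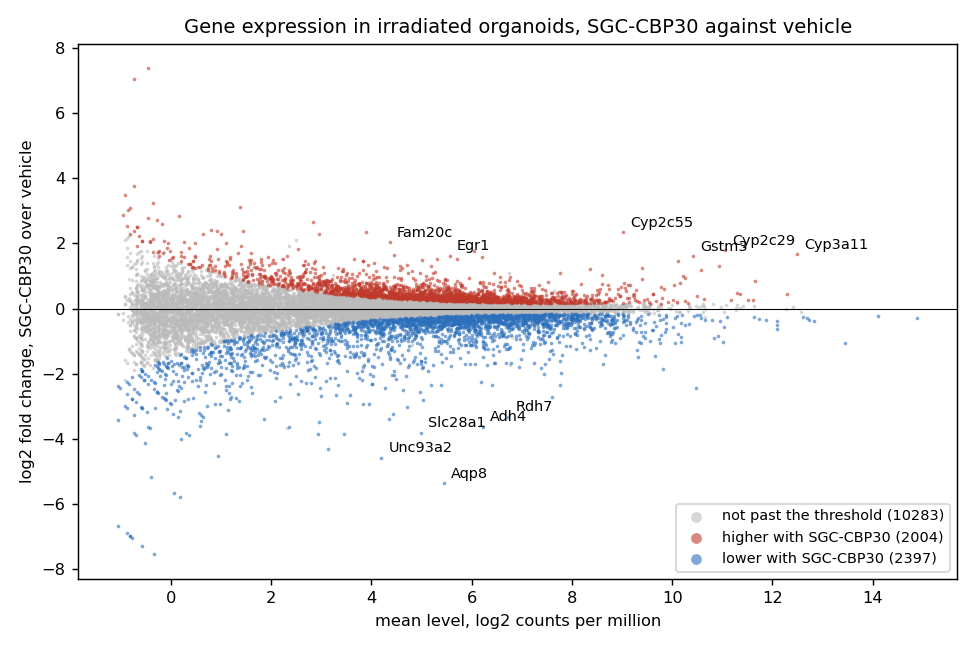
Log2 fold change of SGC-CBP30 over vehicle (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 14684 tested genes, 1 point per gene. Red points are the 2004 higher and blue points the 2397 lower genes, grey points are not past the threshold, and 647 called genes are at least 2-fold lower against 224 at least 2-fold higher, with Aqp8 at -5.37.

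Of the 10 genes that fell most, Aqp8 (ENSMUSG00000030762, chromosome 7, 123462291 to 123468004, plus strand) had a log2 fold change of -5.37 ± 0.14 (SE). It was followed by Unc93a2 at -4.57 ± 0.17, Rdh16 at -4.31 ± 0.24, Lrrc3 at -3.84 ± 0.20 and Slc28a1 at -3.82 ± 0.13. Adh4 (ENSMUSG00000037797, chromosome 3, 138415466 to 138430892, plus strand) fell from 139 ± 2.70 CPM to 11.2 ± 0.536 CPM. Aqp3, a channel for water and glycerol, reached -3.40 ± 0.14, Rdh7 -3.32 ± 0.08, and the adhesion receptor gene Adgrd1 -3.02 ± 0.13. Slc5a4a reached -3.25 ± 0.14, and since its neighbour Slc5a4b is a close copy its own share of the reads is uncertain. All of these coordinates are spans of whole genes on GRCm38, because counts were summed over a gene.

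Of the 10 genes that rose most, Cyp2c55 (ENSMUSG00000025002, chromosome 19, 39007019 to 39042693, plus strand) went from 169 ± 6.77 CPM to 864 ± 17.3 CPM, a log2 fold change of 2.35 ± 0.06 (SE). Cyp3a11 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964, minus strand), which encodes a main drug-metabolizing enzyme of mouse liver and gut, was already abundant at 2746 ± 25.2 CPM and rose to 8710 ± 34.5 CPM. Reads of Cyp2c and Cyp3a members can be shared with close copies. Fam20c, the gene of a secretory pathway protein kinase, rose by 2.04 ± 0.14 on the log2 scale, and Atp11a, the gene of a phospholipid flippase, by 1.76 ± 0.09. Egr1, an immediate early transcription factor gene, rose by 1.63 ± 0.10, and Sprr1a, a cornified envelope gene also induced in regenerating gut epithelium, by 1.60 ± 0.09. Clca4a rose by 1.63 ± 0.15 and Slc37a2 by 1.54 ± 0.09. The glutathione S-transferase gene Gstm3 rose by 1.61 ± 0.08, but its call was lost without SGC-CBP30 replicate 1 (adjusted p = 0.236) or replicate 2 (adjusted p = 0.232), with log2 fold changes of 1.62 and 1.60.

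**Figure D2:**
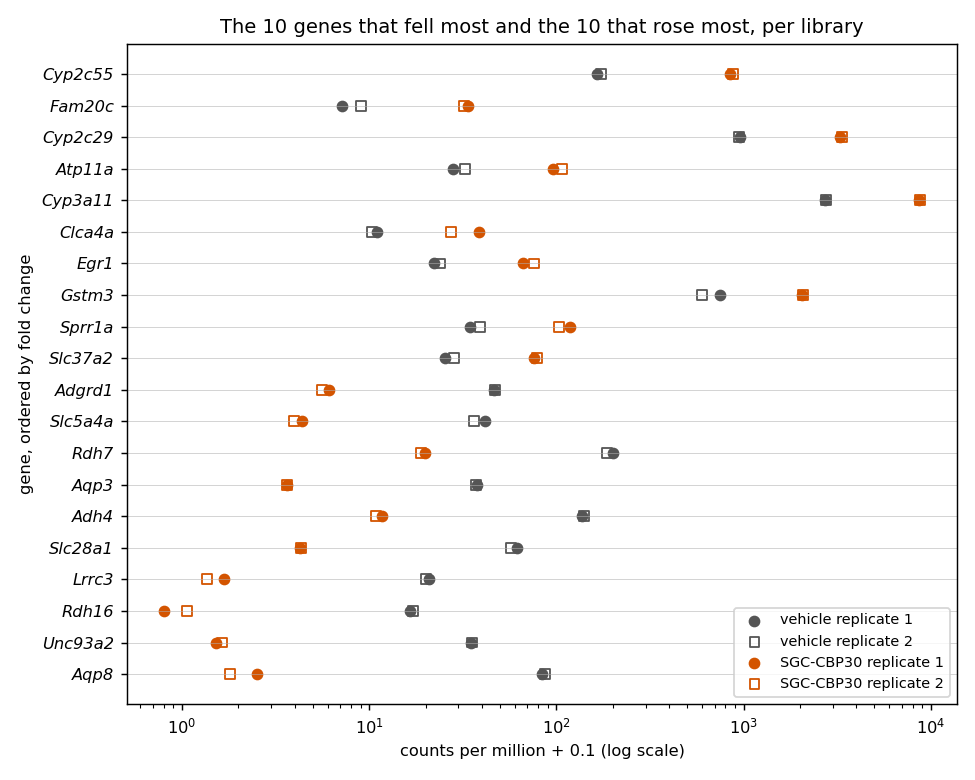
Expression per library of the 10 genes that rose most and the 10 that fell most, in CPM plus 0.1 on a log axis, with vehicle in grey and SGC-CBP30 in orange, replicate 1 as filled circles and replicate 2 as open squares. Only genes whose groups do not overlap were eligible. The changes run from Cyp2c55 at 5.11-fold higher to Aqp8 at 41.3-fold lower.

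The genes of the inhibited proteins differed by little between the groups. Ep300 (ENSMUSG00000055024, chromosome 15, 81585351 to 81652077, plus strand), which encodes p300, rose by 0.24 ± 0.07 (SE) on the log2 scale, from 151 ± 4.32 to 178 ± 11.1 CPM (SD, n = 2). Crebbp (ENSMUSG00000022521, chromosome 16, 4081328 to 4213997, minus strand), which encodes CBP, had a log2 fold change of 0.16 ± 0.08 and was not past the threshold (edgeR adjusted p = 0.154). Among the 39 tested bromodomain and acetyltransferase genes 12 rose, 2 fell and 25 were not past the threshold, and 13 rose and 2 fell when adjusted over the list alone. Those that rose include the chromatin remodelling ATPase genes Smarca2 (0.57 ± 0.09) and Smarca4 (0.50 ± 0.07), the acetyl-lysine reader gene Brd2 (0.51 ± 0.06) and Trim24 (0.39 ± 0.09). As a list they were higher by camera (median log2 fold change 0.15, adjusted p = 0.0131; adjusted p = 0.756 with an estimated correlation). The list's call was lost without vehicle replicate 1 (adjusted p = 0.0691) and without SGC-CBP30 replicate 2 (adjusted p = 0.111), and fry did not make it (adjusted p = 0.130). The Ep300 call was lost without vehicle replicate 1 (adjusted p = 0.174) or 2 (adjusted p = 0.0649), and the log2 fold change of Crebbp was 0.085 and 0.24 without vehicle replicates 1 and 2 and 0.26 and 0.042 without SGC-CBP30 replicates 1 and 2. It passed the threshold without SGC-CBP30 replicate 1 (adjusted p = 0.00164) and with library totals as the scale (adjusted p = 0.0322).

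Genes of the p53 response and of apoptosis were not called as groups, although several cell death genes fell. Trp53 itself (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand) had a log2 fold change of -0.14 ± 0.08 (SE) and was not past the threshold (edgeR adjusted p = 0.193); the log2 fold change was -0.0910 without vehicle replicate 1 and -0.0684 with library totals as the scale. Of 36 p53 target genes 3 rose, 10 fell and 23 were not past the threshold (5 and 11 adjusted over the list alone). The death receptor gene Fas fell by 0.98 ± 0.13 on the log2 scale, Sesn1, a stress-induced regulator of growth signalling, by 0.70 ± 0.09, and the stress cytokine gene Gdf15 by 0.66 ± 0.14. Cdkn1a, the p53-induced cell cycle inhibitor gene, chosen after its values were seen, had 0.11 ± 0.06 and was not past the threshold. Among 18 tested pro-apoptotic effectors 1 rose, 5 fell and 12 were not past the threshold (1 and 5 adjusted over the list alone). The executioner caspase gene Casp6 fell by 1.23 ± 0.08 and the initiator Casp9 by 0.40 ± 0.10, a call lost without vehicle replicate 1 (adjusted p = 0.158, log2 fold change -0.27). Of 11 anti-apoptotic genes Bcl2l2 rose (0.28 ± 0.09), Bag4 fell (-0.52 ± 0.09) and 9 were not past the threshold (1 and 1 adjusted over the list alone). The Bcl2l2 call was lost in DESeq2 (adjusted p = 0.115) and without vehicle replicate 1 (adjusted p = 0.120) or 2 (adjusted p = 0.139). Camera called none of these 3 lists: the p53 targets had a median of -0.038 (adjusted p = 0.535), the pro-apoptotic effectors -0.065 (adjusted p = 0.504), and the anti-apoptotic genes a median of 0.047 with a mean of -0.038 and a camera direction of lower (adjusted p = 0.791).

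Proliferation genes were lower with SGC-CBP30. Of 30 G2 and mitosis genes 17 fell, 0 rose and 13 were not past the threshold, and 18 fell when adjusted over the list alone. The survivin gene Birc5 fell by 0.57 ± 0.12 (SE) on the log2 scale, the mitotic cyclin gene Ccnb1 by 0.51 ± 0.10 and Ube2c, which encodes a ubiquitin-conjugating enzyme of mitotic exit, by 0.42 ± 0.09. The mitotic kinesin gene Kif20a fell by 0.46 ± 0.14, a call lost without SGC-CBP30 replicate 1 (adjusted p = 0.173, log2 fold change -0.30) and in DESeq2 (adjusted p = 0.113). The proliferation marker gene Mki67, chosen after its values were seen, had a log2 fold change of -0.053 ± 0.077 and was not past the threshold. The list was lower by camera (median -0.35, adjusted p = 5.0e-05; adjusted p = 0.558 with an estimated correlation). Of 30 S phase genes 11 fell, 0 rose and 19 were not past the threshold, and 13 fell when adjusted over the list alone. The replication genes Gins1 and Mcm7 fell by 1.19 ± 0.29 and 0.48 ± 0.08, and the nucleotide synthesis gene Rrm1 by 0.48 ± 0.09. This list too was lower by camera (median -0.24, adjusted p = 7.5e-04; adjusted p = 0.558 with an estimated correlation).

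Among 30 DNA double-strand break repair genes 3 rose, 6 fell and 21 were not past the threshold (3 and 6 adjusted over the list alone). The homologous recombination gene Brca1 fell by 1.08 ± 0.11 (SE) on the log2 scale, from 42.7 ± 0.112 to 20.1 ± 2.50 CPM (SD, n = 2). The checkpoint kinase genes Chek1 and Chek2 fell by 0.91 ± 0.22 and 0.51 ± 0.13. The list as a whole was not called (median -0.018, camera adjusted p = 0.791).

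Markers of mature absorptive cells were lower. Of 30 enterocyte markers 21 fell, 2 rose and 7 were not past the threshold, with 21 and 2 when adjusted over the list alone. The sucrase-isomaltase gene Sis fell from 15115 ± 19.4 to 7284 ± 703 CPM (SD, n = 2), the trehalase gene Treh by 1.21 ± 0.06 (SE) on the log2 scale, and the brush border peptidase genes Enpep and Anpep by 1.06 ± 0.06 and 1.03 ± 0.06. The 2 that rose, named after their values were seen, were the apolipoprotein gene Apoa4 (0.43 ± 0.06) and the keratin gene Krt20 (0.43 ± 0.07). The list was lower by camera (median -0.39, adjusted p = 4.9e-05; adjusted p = 0.67 with an estimated correlation). Among 9 tested markers of the distal small intestine and colon 6 fell, 1 rose and 2 were not past the threshold, with 6 and 1 when adjusted over the list alone. The chloride exchanger gene Slc26a3 fell by 0.88 ± 0.07, alongside Aqp8, whereas Cyp2c55 of the same list rose. Car4, the gene of a membrane carbonic anhydrase, had 38 counts in the vehicle libraries together and 0 in the SGC-CBP30 libraries, at least 13.0-fold lower against a floor of 3 counts over the group. The list was lower by camera (median -0.88, and -0.88 with Car4 at its bound, adjusted p = 0.0131; adjusted p = 0.558 with an estimated correlation). That call was lost with the filter of at least 50 counts in 2 libraries (median -0.60, adjusted p = 0.053).

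Markers of 2 of the 4 secretory lineages were lower as lists. Of 21 tested Paneth cell markers 9 fell, 0 rose and 12 were not past the threshold, with 11 lower when adjusted over the list alone. The lysozyme gene Lyz1 fell by 0.38 ± 0.06 (SE) on the log2 scale, the antimicrobial angiogenin gene Ang4 by 0.43 ± 0.06 and Habp2 by 0.99 ± 0.18, and the list was lower by camera (median -0.35, adjusted p = 0.0015; adjusted p = 0.682 with an estimated correlation, and 0.0761 by fry). Without vehicle replicate 1 its median was -0.21 (adjusted p = 0.0079). Of 21 goblet cell markers 7 fell, 1 rose and 13 were not past the threshold (8 and 1 adjusted over the list alone). The chemokine genes Ccl6 and Ccl9 fell by 2.30 ± 0.15 and 2.69 ± 0.23 and the guanylin gene Guca2a by 0.55 ± 0.06, whereas the main mucin gene Muc2, named after its values were seen, rose by 0.24 ± 0.07. The list was lower by camera (median -0.24, adjusted p = 0.0180; adjusted p = 0.558 with an estimated correlation), a call lost without vehicle replicate 1 (adjusted p = 0.0663). Of 25 tested enteroendocrine markers 6 fell, 2 rose and 17 were not past the threshold (6 and 2 adjusted over the list alone), among them the hormone genes Gcg (-0.74 ± 0.11) and Tac1 (-0.62 ± 0.12) and the granin gene Scg2 (-0.85 ± 0.14). Of 17 tested tuft cell markers Trpm5 (-0.72 ± 0.15), a taste transduction channel gene, and Plcg2 (-0.71 ± 0.13) fell and 15 were not past the threshold (2 lower adjusted over the list alone). Camera called neither the enteroendocrine list (median -0.21, adjusted p = 0.149) nor the tuft list (median -0.14, adjusted p = 0.162). The enteroendocrine median was -0.076 without vehicle replicate 1, -0.065 without SGC-CBP30 replicate 2 and -0.14 with library totals as the scale. The tuft median was -0.23 without SGC-CBP30 replicate 1, -0.22 without SGC-CBP30 replicate 2 and -0.070 with library totals.

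**Figure D3:**
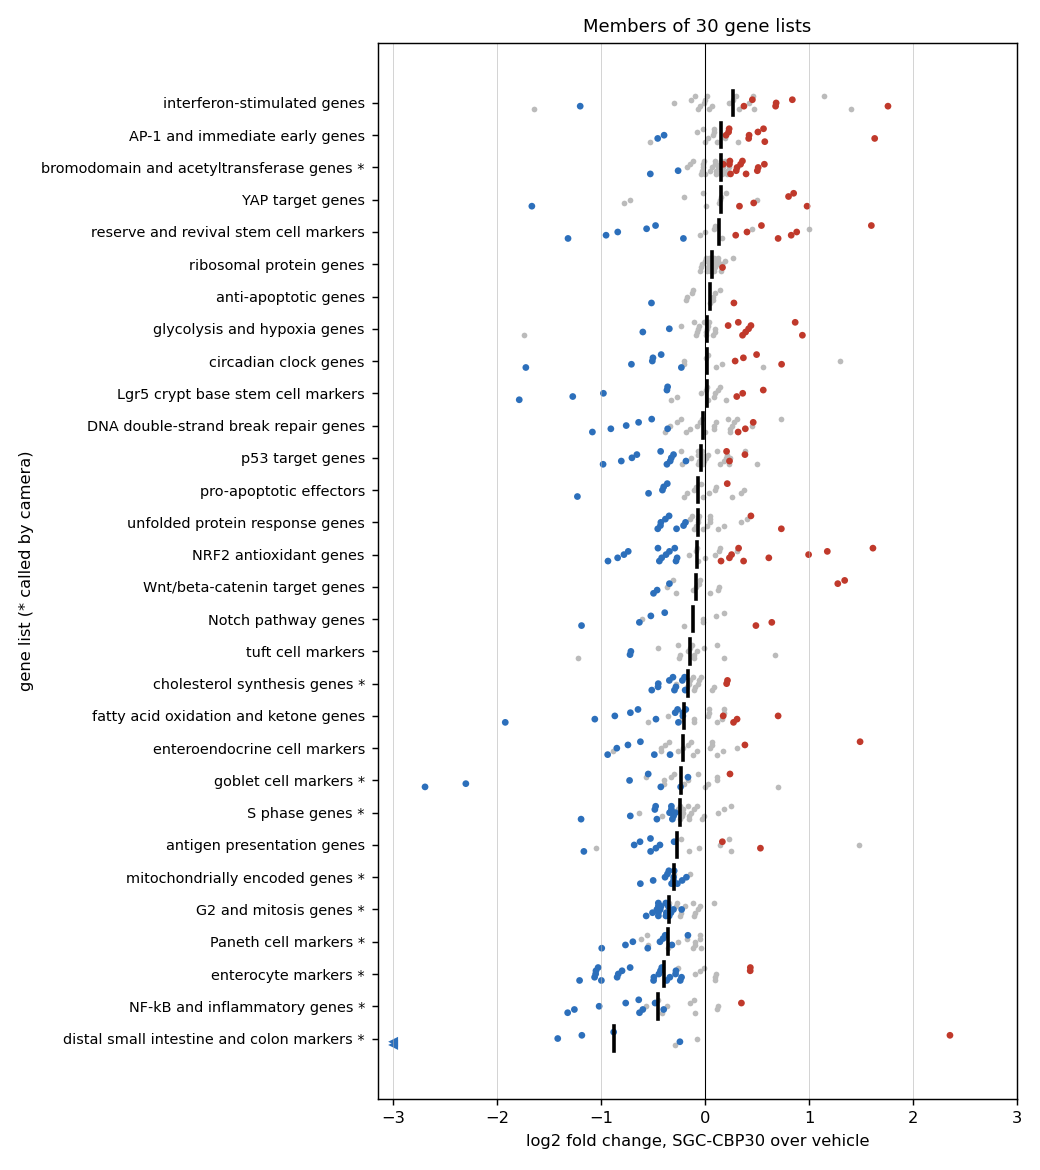
Log2 fold change of SGC-CBP30 over vehicle (horizontal axis) for each tested member of the 30 gene lists (vertical axis, ordered by median). Red and blue points are members called higher and lower, grey points are not past the threshold, black bars are list medians, asterisks mark the 10 lists called by camera, and triangles at -3 stand for 2 members beyond the axis. List medians run from -0.88 for distal small intestine and colon markers to 0.26 for interferon-stimulated genes.

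Stem cell and regeneration markers moved in both directions. Of 19 Lgr5 crypt base stem cell markers 3 rose, 5 fell and 11 were not past the threshold (3 and 5 adjusted over the list alone). Lgr5, the R-spondin receptor gene that defines these cells, rose by 0.56 ± 0.10 (SE) on the log2 scale, while Olfm4 fell by 1.79 ± 0.08, from 192 ± 18.2 to 55.5 ± 1.46 CPM (SD, n = 2), and Aqp4 by 1.27 ± 0.13. The list's median of 0.014 and its mean of -0.18 differ in sign, and camera, with a direction of lower, did not call it (adjusted p = 0.763). Of 20 tested reserve and revival stem cell markers 7 rose, 6 fell and 7 were not past the threshold (7 and 6 adjusted over the list alone). Sprr1a rose as given above, the tissue factor gene F3 by 0.88 ± 0.10 and the keratin gene Krt7 by 0.83 ± 0.07. Of the 6 that fell, Ly6a reached -1.32 ± 0.16, Il33 -0.95 ± 0.17 and Ereg -0.84 ± 0.12. Clu had 0.16 ± 0.11 and was not past the threshold. Ly6a, Il33, Ereg and Clu were named after their values were seen. The list was not called (median 0.13, camera adjusted p = 0.370). Its median was 0.20 without SGC-CBP30 replicate 1 or with library totals as the scale, and 0.078 without SGC-CBP30 replicate 2 and 0.080 with the filter of at least 50 counts in 2 libraries. Of 16 tested YAP target genes 5 rose, 1 fell and 10 were not past the threshold (5 and 1 adjusted over the list alone), with Ctgf at 0.98 ± 0.22, Ajuba at 0.80 ± 0.14 and Tead1 at 0.47 ± 0.12. The list was not called (median 0.15, camera adjusted p = 0.149), except with the filter of at least 50 counts in 2 libraries (median 0.18, adjusted p = 0.0199), and the Tead1 call was lost without vehicle replicate 1 (adjusted p = 0.0879).

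Of 15 tested Wnt/beta-catenin targets 2 rose, 3 fell and 10 were not past the threshold (2 and 3 adjusted over the list alone). The intestinal homeobox gene Cdx1 fell by 0.46 ± 0.08 (SE) on the log2 scale, Lrp4 by 0.50 ± 0.09, and the growth regulator gene Myc by 0.34 ± 0.08, a call lost without vehicle replicate 1 (adjusted p = 0.0904). The 2 that rose, named after their values were seen, were Bambi (1.27 ± 0.32) and Apcdd1 (1.34 ± 0.48). Both were scarce, at 1.78 and 0.783 CPM in vehicle. The list's median was -0.086 and its mean 0.023, opposite in sign, with a camera direction of lower (adjusted p = 0.752). Of 12 tested Notch pathway genes 2 rose, 4 fell and 6 were not past the threshold (2 and 5 adjusted over the list alone). The ligand gene Jag1 fell by 0.63 ± 0.11, and the receptor gene Notch2 and the co-activator gene Maml1 rose by 0.64 ± 0.13 and 0.49 ± 0.10. The Notch list was not called (median -0.11, camera adjusted p = 0.469), and its median moved from -0.021 without SGC-CBP30 replicate 1 to -0.23 without SGC-CBP30 replicate 2.

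NF-kB and inflammatory genes were lower as a list, and the cells they fell in were not resolved. Csf1r and Vim, markers of other cell types, fell too, each the 1 of 3 tested markers of its list to pass. Such markers were scarce. In vehicle Csf1r had 2.69 CPM and Vim 16.1 CPM, against 2768 CPM for Pigr but 2.31 CPM for Duoxa2 of the inflammatory list. Of 19 tested NF-kB and inflammatory genes 9 fell, 1 rose and 9 were not past the threshold, the same counts of 9 and 1 as when adjusted over the list alone. Pigr, which encodes the receptor that carries IgA across the epithelium, fell from 2768 ± 48.2 to 1365 ± 10.4 CPM (SD, n = 2), the cytokine gene Il18 by 0.64 ± 0.07 (SE) on the log2 scale, and Tnfaip3, an NF-kB feedback inhibitor gene, by 0.76 ± 0.11. Duoxa2, needed for the hydrogen peroxide producing oxidase DUOX2, fell by 1.32 ± 0.44, but this call was lost in DESeq2 (adjusted p = 0.153), without vehicle replicate 1 (adjusted p = 0.464, log2 fold change -0.75) and without SGC-CBP30 replicate 2 (adjusted p = 0.0686). The list was lower by camera (median -0.45, adjusted p = 0.0027; adjusted p = 0.558 with an estimated correlation). Of 18 tested antigen presentation genes 8 fell, 2 rose and 8 were not past the threshold (8 and 2 adjusted over the list alone). The light chain gene B2m fell by 0.47 ± 0.06 and H2-T3 by 0.52 ± 0.08, whereas H2-D1 rose by 0.53 ± 0.07, with reads that similar histocompatibility genes can share, and the list was not called (median -0.27, camera adjusted p = 0.135).

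Of 27 tested interferon-stimulated genes 6 rose, 1 fell and 20 were not past the threshold (6 and 1 adjusted over the list alone). The transcription factor gene Irf7 rose by 0.68 ± 0.11 (SE) on the log2 scale and Oasl1 by 0.45 ± 0.08, while the antiviral gene Mx1 fell by 1.20 ± 0.20. The list was not called (median 0.26, camera adjusted p = 0.138), except without SGC-CBP30 replicate 2 (median 0.37, adjusted p = 0.0093). Its median fell to 0.056 without SGC-CBP30 replicate 1 (adjusted p = 0.743) and to 0.13 with the filter of at least 50 counts in 2 libraries. Of 22 tested AP-1 and immediate early genes 9 rose, 2 fell and 11 were not past the threshold (10 and 2 adjusted over the list alone). Egr1 rose as given above and Jun, an AP-1 subunit gene, by 0.57 ± 0.11, while the antiproliferative gene Btg1 fell by 0.46 ± 0.06. This list was not called either (median 0.15, camera adjusted p = 0.0748), except without vehicle replicate 2 (median 0.21, adjusted p = 0.0463) or SGC-CBP30 replicate 2 (median 0.26, adjusted p = 0.0093), and its median was 0.096 without SGC-CBP30 replicate 1 (adjusted p = 0.495).

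Metabolic genes moved in both directions. Of 24 cholesterol synthesis genes 10 fell, 2 rose and 12 were not past the threshold (12 and 2 adjusted over the list alone). Hmgcs1, the gene of an early enzyme of the pathway, fell by 0.45 ± 0.06 (SE) on the log2 scale, Cyp51 by 0.31 ± 0.06, Pmvk by 0.45 ± 0.09, and the sterol sensor gene Insig1 by 0.51 ± 0.06. The list was lower by camera (median -0.17, adjusted p = 0.0181; adjusted p = 0.702 with an estimated correlation), a call lost without vehicle replicate 1 (adjusted p = 0.0617), vehicle replicate 2 (adjusted p = 0.102) or SGC-CBP30 replicate 2 (adjusted p = 0.0794) and with library totals as the scale (median -0.093, adjusted p = 0.0569). It was also lost by fry (adjusted p = 0.0761) and after a genome-wide trend on gene length, GC content and level was removed (median -0.10, adjusted p = 0.0763). Of 28 tested fatty acid oxidation and ketone genes 12 fell, 4 rose and 12 were not past the threshold (12 and 5 adjusted over the list alone). The fatty acid transporter gene Cd36 fell by 1.92 ± 0.12, the lipase inhibitor gene Angptl4 by 1.06 ± 0.09 and the peroxisomal enzyme gene Ehhadh by 0.65 ± 0.06. This list was not called (median -0.20, camera adjusted p = 0.138), except without SGC-CBP30 replicate 1 (median -0.21, adjusted p = 0.0243). Its median was -0.032 without SGC-CBP30 replicate 2 (adjusted p = 0.624), -0.13 with library totals as the scale and -0.095 after the trend was removed.

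Of 30 NRF2 antioxidant genes 9 rose, 12 fell and 9 were not past the threshold (10 and 13 adjusted over the list alone). The glutathione S-transferase gene Gstm1 and the efflux pump gene Abcc2 rose by 1.17 ± 0.06 (SE) and 0.99 ± 0.06 on the log2 scale, and the catalase gene Cat fell by 0.78 ± 0.06. The list was not called (median -0.074, camera adjusted p = 0.654). Of 26 glycolysis and hypoxia genes 8 rose, 2 fell and 16 were not past the threshold, as when adjusted over the list alone. The hexokinase gene Hk1 rose by 0.93 ± 0.09 and the glucose transporter gene Slc2a1 by 0.44 ± 0.07, and the carbonic anhydrase gene Car9 fell by 0.60 ± 0.06, with no call for the list (median 0.019, camera adjusted p = 0.430). Of 26 unfolded protein response genes 8 fell, 2 rose and 16 were not past the threshold, also as when adjusted over the list alone. The chaperone gene Canx fell by 0.35 ± 0.06 and Manf by 0.46 ± 0.08, and the asparagine synthetase gene Asns rose by 0.44 ± 0.08 (list median -0.067, camera adjusted p = 0.430). Of 18 tested circadian clock genes 4 rose, 6 fell and 8 were not past the threshold, with 4 and 6 when adjusted over the list alone. Npas2 and Hlf fell by 0.71 ± 0.09 and 1.72 ± 0.25, and the list's median of 0.017 and mean of -0.025 differ in sign, with a camera direction of lower (adjusted p = 0.791).

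Mitochondrially encoded transcripts were lower, as was their share of counts given above. Of 14 tested genes 12 fell, 0 rose and 2 were not past the threshold, and 12 fell when adjusted over the list alone. The complex I gene mt-Nd1 fell by 0.39 ± 0.06 (SE) on the log2 scale, mt-Cytb by 0.35 ± 0.06, mt-Co3 by 0.62 ± 0.11 and mt-Atp6 by 0.50 ± 0.12, and the list was lower by camera (median -0.30, adjusted p = 0.0020; adjusted p = 0.682 with an estimated correlation). Fry did not call it (adjusted p = 0.0804), and removing the trend on gene length, GC content and level took the median to -0.19 (camera adjusted p = 0.0299). Nuclear copies of mitochondrial genes can share these reads. In vehicle, mt-Co3 and mt-Atp6 had 34.2 and 29.1 CPM, against 8207 CPM for mt-Nd1 and 7571 CPM for mt-Cytb. Their larger falls thus rest on far fewer counts. Of 30 ribosomal protein genes Rps2 rose (0.16 ± 0.06) and 29 were not past the threshold, and 0 changed when adjusted over the list alone. The Rps2 call was lost in DESeq2 (adjusted p = 0.0505), with the filter of at least 50 counts in 2 libraries (adjusted p = 0.054), and without vehicle replicate 1 (adjusted p = 0.187) or 2 (adjusted p = 0.449). The ribosomal list was not called (median 0.063, camera adjusted p = 0.149), except with library totals as the scale (median 0.14, adjusted p = 0.0400), without SGC-CBP30 replicate 2 (median 0.13, adjusted p = 0.0093) and after removal of the trend on gene length, GC content and level (median 0.17, adjusted p = 0.0033).

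Markers of cells other than epithelium were scarce in both groups. Only 3 of 17 mesenchymal, 3 of 19 blood and immune, and 4 of 16 endothelial and neural markers had enough counts to be tested, too few for a list test. The collagen gene Col1a1 had 11 counts and the leukocyte gene Ptprc 24 over all 4 libraries, both chosen after their values were seen. The vimentin gene Vim fell from 16.1 ± 0.692 to 9.61 ± 0.705 CPM (SD, n = 2), 1 of 3 mesenchymal markers to pass, and the macrophage receptor gene Csf1r from 2.69 ± 0.438 to 0.695 ± 0.0973 CPM, 1 of 3 blood and immune markers. Of 4 endothelial and neural markers the receptor tyrosine kinase gene Ret rose from 8.66 ± 0.0108 to 17.3 ± 0.472 CPM and S100b fell from 1.34 ± 0.138 to 0.376 ± 0.0325 CPM. Adjusted over the list alone, these 3 lists gave 1, 1 and 2 changed genes. The S100b call was lost in DESeq2 (adjusted p = 0.132) and without any 1 of the 4 libraries (adjusted p from 0.0704 to 0.172).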

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

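The alternatives here were fixed before the data were examined, except cameraPR and the removal of a trend on gene length, GC content and level, which were added after seeing the data. No called gene changed sign under any of the 12 other fits to the genes, and of the 119 named genes' values under them 1398 kept direction and side of the threshold, 24 lost their call and 2 gained one. The count of 4401 changed genes became 2722 in DESeq2, of which 2718 were shared and 1070 were higher. It was 2894 at an adjusted p under 0.01 and 871 at a change of at least 2-fold. Leaving out each library in turn gave 2899 to 4557 changed and 1235 to 2104 higher genes, with the lowest counts without a vehicle library; the cause was not tested. Without SGC-CBP30 replicate 2, whose label carries another compound name, 4557 genes changed. The other fits gave 4162 to 4831. With the replicate block 4703 genes changed, 4386 of them shared, and all 10 list calls held. The numbers were not taken to pair the libraries: the deviations of equal-numbered libraries correlated at -0.0244 across genes.

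Of the 10 list calls, 0 remained with an estimated correlation. That setting found 0 of 10 shifted lists in simulated data, so a call missing under it cannot tell a shifted list from an unshifted one. Genes there were drawn independently, so false calls among correlated genes were not checked. In the data the estimated correlations of the called lists ran from -0.11 for distal markers to 0.30 for mitochondrial genes. The goblet and NF-kB lists, with estimates of -0.014 and -0.030, lost their calls under that setting too (camera adjusted p = 0.558 for each). A positive correlation was thus not needed for a loss. Fry also called 6 of the 10, but not Paneth (adjusted p = 0.0761), cholesterol (adjusted p = 0.0761), bromodomain (adjusted p = 0.130) and mitochondrial genes (adjusted p = 0.0804). CameraPR called 1 of the 10, the distal markers (adjusted p = 2.2e-11). It gave adjusted p = 0.0587 for enterocyte, 0.0995 for NF-kB, 0.164 for goblet, 0.191 for Paneth, 0.235 for G2 and mitosis, 0.322 for S phase and for bromodomain, 0.354 for mitochondrial and 0.681 for cholesterol genes. The 9 distal members, of which 6 fell and 1 rose, include Aqp8 at -5.37 and Car4. Car4 was fitted at -7.27 with 0 counts in the SGC-CBP30 libraries. Its bound against the floor of 3 counts was -3.70, and the cameraPR value was not recomputed at that bound. With the trend removed 10 lists were called, 9 of them shared: cholesterol genes were lost (adjusted p = 0.0763) and ribosomal proteins gained (adjusted p = 0.0033). Some medians of uncalled lists changed sign. Library totals as the scale moved the median log2 fold change of all genes from 0.0096 to 0.083, and small negative list medians with it: the p53 targets had 0.035, the pro-apoptotic effectors 0.0076, double-strand break repair 0.055 and the unfolded protein response 0.0056. The cause of the other sign changes was not tested. With at least 50 counts in 2 libraries, circadian clock genes had -0.011. With the trend removed, NRF2 genes had 0.020 and the unfolded protein response 0.011. Leaving out each library in turn, medians ran from -0.059 to 0.024 for anti-apoptotic genes, -0.063 to 0.096 for double-strand break repair, -0.027 to 0.039 for circadian clock genes, -0.045 to 0.056 for Lgr5 crypt base markers, -0.21 to 0.049 for Wnt/beta-catenin targets, -0.061 to 0.013 for p53 targets, -0.089 to -0.032 for pro-apoptotic effectors, -0.11 to -0.046 for the unfolded protein response, -0.031 to 0.10 for glycolysis and hypoxia, -0.020 to 0.13 for ribosomal proteins and -0.12 to 0.012 for NRF2 genes. In data simulated at this depth with 2 libraries per group, 22% of genes with the smallest change tried were found. Only 200 genes were changed there, against 4401 called in the data, so the cutoff in unadjusted p was stricter. That share need not hold for the data. Depth was not varied.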

Other observations

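The tests of 20 gene families defined by symbol and of the enterocyte share, and the reported version of the test of gene length and GC content, were chosen after the results were seen, and so were the genes named in the families. The test of xenobiotic receptor targets and that of paralogs were written before their own results were seen, though after the data had been seen.

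Of 38 tested proteasome subunit genes 24 rose, 3 fell and 11 were not past the threshold (median log2 fold change 0.24, camera adjusted p = 1.1e-04 over the families; adjusted p = 0.495 with an estimated correlation), with Psmd4 at 0.48 ± 0.07 (SE) and Psma4 at 0.44 ± 0.07. The 3 that fell were Psmb8 (-0.43 ± 0.16), Psmb9 (-0.53 ± 0.17) and Psmb10 (-0.30 ± 0.09), the catalytic subunits of the immunoproteasome, which cuts peptides for antigen presentation. Solute carrier genes went the other way: 118 of 272 fell and 30 rose (median -0.23, adjusted p = 1.1e-04; adjusted p = 0.273 with an estimated correlation). Of 12 carboxylesterase genes 10 fell, such as Ces1f (-1.68 ± 0.07), and Ces2a alone rose (1.45 ± 0.06), in a family whose copies can share reads (median -1.06, adjusted p = 1.5e-04; adjusted p = 0.434 with an estimated correlation). Of 16 aldehyde dehydrogenase genes 8 fell and 2 rose (median -0.20, adjusted p = 0.0393; adjusted p = 0.707 with an estimated correlation), and of 46 cytochrome P450 genes 21 fell and 11 rose (median -0.37, adjusted p = 0.0454; adjusted p = 0.434 with an estimated correlation).

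Of 14 tubulin genes 6 rose, led by Tubb2a at 1.35 ± 0.12 (SE), and 1 fell (median 0.25, adjusted p = 0.0191; adjusted p = 0.495 with an estimated correlation). Of 14 histone genes 3 rose and 0 fell, among them Hist1h1c at 0.83 ± 0.09 (median 0.77, adjusted p = 2.8e-04; adjusted p = 0.434 with an estimated correlation). Zfp zinc finger genes were slightly higher, with 32 of 328 up and 11 down (median 0.12, adjusted p = 0.0106; adjusted p = 0.434 with an estimated correlation), and UDP-glucuronosyltransferase genes lower, with 4 of 14 down and 1 up (median -0.35, adjusted p = 0.0218; adjusted p = 0.482 with an estimated correlation). The medians of the 9 families named here kept their sign with DESeq2 size factors and with library totals. Their size moved, however: with library totals the aldehyde dehydrogenase median was -0.13 and the Zfp median 0.19. The other 11 families were not called. Clock genes, named here after their values were seen, moved in both directions: Arntl (-0.42 ± 0.10), Npas2 and Cry1 (-0.51 ± 0.10) fell, while Per3 (0.49 ± 0.11), Nr1d1 (0.29 ± 0.11) and Dbp (0.73 ± 0.25) rose.

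The rise of Cyp2c55, Cyp2c29 and Cyp3a11 was weighed against reads shared between paralogs, which would move reads within a family and leave its sum in place. The summed counts rose for the Cyp2c family (log2 fold change 1.45 ± 0.019 SE) and for the Cyp3a family (1.35 ± 0.021, the smaller of the sums). This argues against reads moved within a family as the whole cause of the rise. The sums include the named genes themselves, so they cannot show which member of a family the added reads came from. Activation of the xenobiotic receptors PXR and CAR is a candidate explanation that stays open: of 21 tested other targets 10 rose, such as Cyp2b10, Alas1 and Abcb1a, but 7 fell, such as Ces2b, and camera, the test set for them, gave p = 0.151 (median 0.11; p = 0.256 with an estimated correlation), while fry, which does not compare the list with other genes, gave p = 0.00312. Whether the compound acts through bromodomains or otherwise here was not tested.

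The fall of enterocyte markers was weighed against a smaller share of enterocytes as the only cause, which would lower all of the markers by about the same fold. The SD of the members' log2 fold changes was 7.48 times their median SE, and Apoa4 and Krt20 rose. Such a spread argues against a smaller share alone only if every marker is expressed by enterocytes alone and evenly among them. That was not tested, so a smaller share, a changed state of these cells, or both together may remain. The treatment itself is the difference the design names. A bias by gene length or GC content was tested by removing the genome-wide trend, which explained 1.59% of the variance of fold changes: the median went from -0.39 to -0.30 ± 0.10 (SE) and camera still called the list (adjusted p = 1.6e-04; uncorrected, adjusted p = 0.67 with an estimated correlation), which argues against that bias as the whole cause. That SE is taken over the list's genes as if they were independent, and it holds no spread between libraries. Leaving out each library in turn, the uncorrected median ran from -0.45 to -0.36. The same correction ended the cholesterol call (adjusted p = 0.0763), brought the ribosomal list past the threshold (adjusted p = 0.0033) and took the mitochondrial median from -0.30 to -0.19. This test and criterion replaced a first version, after the result of that version was seen. The first version too was written after the data had been seen, though before it was run. The first version asked for a median below -0.2, which the corrected median was by slightly less than its SE, and its list test, limma's cameraPR on the edgeR fold changes, did not call the list before the correction (adjusted p = 0.0587) or after it (adjusted p = 0.0838). It left the question open.

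The rise of bromodomain and acetyltransferase genes, long transcripts with a median length of 8521 bases against 3859 for all genes, was weighed against the same bias. After the trend was removed the median was 0.17 ± 0.04 (SE), against 0.15 before, and camera still called the list (adjusted p = 0.0230, against 0.0131 before; uncorrected, adjusted p = 0.756 with an estimated correlation), which argues against the bias as the whole cause. Here too the SE is taken over the list's genes as if independent. Leaving out each library in turn, the uncorrected median ran from 0.10 to 0.19. The first version of this test, with cameraPR, also replaced after the results were seen, did not call the list before the correction (adjusted p = 0.322) or after it (adjusted p = 0.508) and so left the question open. A response of these genes to the inhibitor may be one hypothesis, which these libraries cannot separate from other effects of treatment, and the call is lost without vehicle replicate 1 (adjusted p = 0.0691) or SGC-CBP30 replicate 2 (adjusted p = 0.111).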
